A study of Mus musculus with 14 samples.

How the data were processed

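The samples were 14 libraries of genomic DNA from mouse CD4 T cells polarised in culture, 3 each of Th0, Th1, Th2 and Th17 and 2 of Th17-noTGFb. Per the labels, DNA was sheared to about 10 kb, prepared by ligation, enriched with Cas9 for a panel of 10 genes and sequenced on nanopore flow cells, and the panel genes are not named. The labels mention data on Treg cells, which were not used here. The deposited tables hold, per the column layout and the values, counts of calls per CpG in 18 columns with strands combined and 2 entries per CpG, for 5hmC and for 5mC. The deposited percent column equals the calls of the modification over the valid calls. Valid calls were the sum of 5mC, 5hmC and unmodified calls in every entry. Genome build mm10 and SAMtools 1.13 were taken from the submitters' processing notes. The basecaller, the modification caller and the aligner are not given in the sources used here. No normalisation had been applied to the counts by the authors as far as the values show.

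The 5mC share was computed as 5mC calls over valid calls, summed over the CpGs of a unit, and the 5hmC share in the same way. Units were 100-kb tiles, 1-kb windows, 5-kb windows around listed genes, and gene regions. The tile size followed a rule on coverage, the smallest of 5, 10, 20, 50 and 100 kb at which most tiles hold at least 10 calls in every library. None did, so 100 kb was used. Listed-gene windows took in 20 kb on each side of the genes and were planned at 2 kb. The plan named 5 kb or the tile size if most did not hold at least 10 calls in every library. Only 3.63% of windows of 2 kb and 4.14% of those of 5 kb did, and 5 kb was used. A unit was tested if every library held at least 10 calls. Chromosome Y, chrM and unplaced sequences were left out of the tests. Gene positions came from a RefSeq annotation of the same build, which carries no strand or exons here. A gene region was therefore the protein-coding gene with 5 kb on both sides, not from upstream of its start as planned, and feature classes used the distance of 1 kb to either gene end. A unit was named by the protein-coding gene it overlaps or the nearest within 50 kb. Units given as having no gene have no protein-coding gene within 50 kb, and other kinds of gene were not looked up.

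Tests used edgeR 4.0.16 in R 4.3.3, with quasi-likelihood fits to methylated and unmethylated counts. Each library had a coefficient for its total and each group a coefficient for the methylated share, and all 14 libraries were in a single fit because the groups have 2 or 3 libraries. P-values were two-sided and adjusted by Benjamini-Hochberg over the units of a comparison, with a threshold of 0.05. The comparisons were Th1, Th2 and Th17 against Th0 and against each other, Th17-noTGFb against Th17 and Th0, and a test over Th0, Th1, Th2 and Th17 for 5hmC and for listed-gene windows. Global shares were compared by exact permutation tests, two-sided. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, on log2 ratios of methylated to unmethylated calls with 1 added to each. There were 16 lists of 251 genes, all found in the annotation. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

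The groups, the tests, the tile rule, the gene lists, the named genes and most alternatives were fixed before the data were examined. The 1-kb windows across the genome, the 2-kb and 1-kb windows around listed genes, 2 kb around gene ends, the refits without run 1, the counting of 5mC with 5hmC, the global level outside deep tiles, and the position of Th17-noTGFb over 1-kb windows were chosen after the coverage or the results had been seen. The 1-kb windows were added because few tiles of 100 kb could be tested and the deep loci span a few kb. Genes were named by a rule. In each comparison these are the called tiles without overlap between groups that have the 10 largest falls and 10 largest rises, the same for gene regions, every listed-gene window called, and Ifng, Tbx21, Il4, Il5, Il13, Gata3, Il17a, Il17f, Foxp3, Il2ra, Ctla4, Il10 and Maf whatever their result. A further gene under this rule is not reported here, and counts of windows include it. The rule was applied to the 1-kb windows too, and fewer were named where space required. Drc1, Otof, Itgb8, Fignl2, Rab2a, Dmxl1, Ppp1r3f and the tiles and regions called only in a refit were named after their values were seen.

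Alternatives were minimums of 5 and 20 calls, limma on the log2 ratios, an offset for each library's global level, a block for the replicate number, fits of only the groups compared, and refits without each library in turn. The labels pair libraries, since replicate 1, 2 and 3 of each group carry the name of run 1, 2 and 3. The pairing was checked on 1-kb windows after the group means were taken off. Libraries of the same run correlated with a mean r of 0.146 over 18 pairs (-0.0663 to 0.337) and those of different runs with a mean of -0.0721 over 36 pairs, and 10 of 12 libraries were closest to a library of their own run. These correlations are across windows, which are not independent. Blocked values are therefore given for the counts, and for some of the single windows, tiles and regions called only with the block.

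The procedure was tested on simulated data with the coverage of all 14 libraries and the mean 5mC of each unit over them. Changes were put into Th2, which was compared with Th0. Simulated libraries were drawn independently, with a single spread for each kind of unit and no run effect. False calls under the run pairing given above were therefore not simulated. Of 523 windows of 1 kb, 200 were given a change, and 18% of changes of 10 points and 52% of changes of 20 points were called, with 0 false calls among 70. In 100-kb tiles 0% and 30% were called, in gene regions 10% and 30%, and in listed-gene windows 20% and 60%. Calls from the same molecule are not independent, and between replicates the chi-square per window was 1.69 to 3.51 where sampling alone gives about 1. The spread between libraries, not the number of calls, was used as the error. Depth per library ran from 442118 to 1770021 valid calls, and 3.25% to 4.51% of calls had failed the caller's threshold and were not counted.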

Results

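DNA methylation was read directly from single molecules by nanopore sequencing in 14 libraries of mouse CD4 T helper cells. Naive CD4 T cells from Foxp3-GFP reporter mice, labelled male, had been sorted, activated through CD3 and CD28 and cultured under conditions that steer them to a helper fate. Th0 (neutral), Th1, Th2 and Th17 cells had 3 libraries each, and the replicate number matched the sequencing run. A further group, Th17-noTGFb, was made under Th17 conditions without TGF-beta, has 2 libraries, and was sequenced alone in run 4. Each table gave, per CpG, the calls of 5-methylcytosine (5mC), of 5-hydroxymethylcytosine (5hmC) and of unmodified cytosine on mm10. The number of valid calls ran from 442118 in Th2 library 1 to 1770021 in Th17 library 2, over 352174 and 1444812 CpGs. Between 89.8% and 94.4% of the covered CpGs were read once. The labels name no separate animals or cultures, so p-values measure the spread between these samples.

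Coverage was concentrated at few loci, genes of helper fate among them, and most of the genome could not be compared. Only 131 of the 26322 tiles of 100 kb and 523 of the 2631383 windows of 1 kb on the autosomes and X held at least 10 calls in every library. Depth stood above 5 times the library median in 202 of the 100-kb tiles, which took 17.3% to 35.2% of the calls on the autosomes and X, and 113 of these reached the minimum in every library. The tile with Maf was read 372 times as deeply as the library median, that with Gata3 245 times, that with Il4, Il13 and Rad50 209 times, that with Tbx21 202 times, that with Il10 108 times and that with Ifng 93.3 times. The Zfp362, Foxp3 and Il17a tiles stood at 96.8, 65.1 and 55.5 times the median. Deeply read tiles with no listed helper gene included Drc1 and Otof at 130 times and Itgb8 at 98.6 times. In the 202 tiles together 5mC averaged 68.4% of calls over the 14 libraries.

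Th2 cells were compared with Th0 to find methylation that goes with Th2 polarisation, and the losses lay at Il4 and Gata3. Il4 encodes the cytokine that defines Th2 cells and lies on chromosome 11 from 53612460 to 53618665. Inside it, at 53617001 to 53618000, 5mC was 86.1% ± 3.32 (SD, n = 3) in Th0 and 32.2% ± 2.89 (SD, n = 3) in Th2 (adjusted p 3.42e-08, median 598 and at least 224 calls per library). The next window but one, 53615001 to 53616000, went from 91.3% ± 0.514 to 69.5% ± 1.08 (adjusted p 6.56e-08, at least 602 calls). Gata3, on chromosome 2 from 9857078 to 9887953, encodes the transcription factor that directs the Th2 programme. Its window 9868001 to 9869000 went from 87.5% ± 1.54 to 70.2% ± 2.38 (adjusted p 5.62e-05, at least 262 calls) and 9873001 to 9874000 from 35.6% ± 2.71 to 15.1% ± 1.99 (adjusted p 0.000474, at least 120 calls). About 4 kb past the annotated end of Il10, a cytokine gene that Th2 cells also express, 5mC at 131029001 to 131030000 on chromosome 1 went from 91.9% ± 6.45 to 57.4% ± 8.30 (adjusted p 0.00153), on as few as 10 calls in a library.

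With edgeR, 16 of the 523 windows of 1 kb were called lower in Th2 than in Th0 and 0 higher, against 52 at an unadjusted p under 0.05, and limma called 14. They included 7 windows at Il4, 7 at Gata3 and 1 at Il10, with differences from -3.18 to -53.8 percentage points at Il4 and from -5.40 to -24.6 at Gata3. All 16 were lower in each of the 3 runs, and the Th0 and Th2 libraries did not overlap. Windows without overlap made up 14.5% of the 523, where chance gives 10%. Leaving out each library in turn kept 12 of the 16. The Il4 window 53612001 to 53613000 was lost without Th0 1, Th0 3, Th2 1, Th2 2 or Th2 3 (adjusted p 0.0954 to 0.190), the Gata3 window at 9869001 without Th0 3 (0.0715), Th2 1 (0.0559) or Th2 3 (0.0656), and the Gata3 window at 9871001 without Th0 3 (0.104), Th2 1 (0.0954) or Th2 2 (0.263). The 100-kb tiles, whose size had been set by a rule before the data were examined, gave 1 call. This was the Il4 tile from 53600001 to 53700000, at 90.5% ± 0.207 in Th0 and 74.8% ± 1.5 in Th2 (edgeR adjusted p 2.1e-06). The Il4 gene region held a median of 9438.5 calls per library, against 13 at Il13 and 24 at Rad50. The tile therefore largely counts the same calls as the Il4 windows and says little about Il13 or Rad50. Without Th0 2 or Th2 3 a tile with no gene on chromosome 14 from 92000001 was called as well (14.2 and 13 points higher, adjusted p 0.0382 and 0.0199), and without Th0 3 the Dmxl1 tile (23.5 points higher, adjusted p 0.0490).

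**Figure D1:**
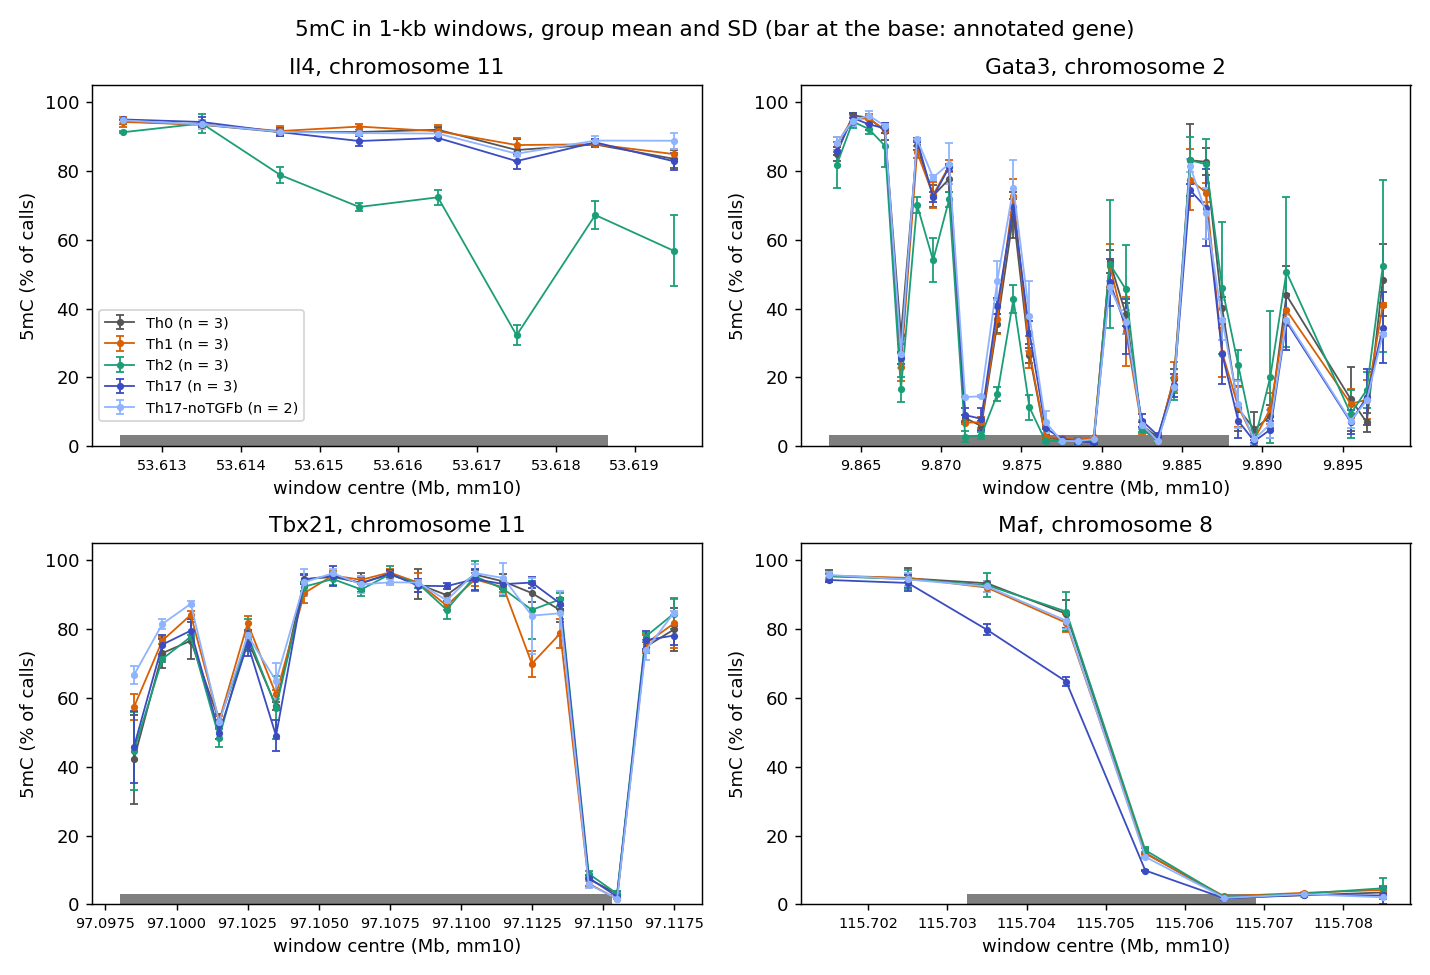
Share of calls that are 5mC (%) along the 1-kb windows tested at Il4, Gata3, Tbx21 and Maf, by window centre in Mb on mm10. Points are group means with SD bars (n = 3, n = 2 for Th17-noTGFb) and the bar at the base marks the annotated gene. Th2 libraries dip to 32.2% at Il4, Th1 libraries to 70.0% at the Tbx21 window from 97112001, and Th17 libraries to 64.8% at the Maf window from 115704001, where Th17-noTGFb stands at 82.5%.

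5hmC, an oxidised form that can precede loss of methylation, was higher in Th2 at Il4. In the window 53615001 to 53616000 it made up 3.26% ± 0.253 (SD, n = 3) of calls in Th2 and 0.872% ± 0.286 in Th0, 1.17% ± 0.192 in Th1 and 1.43% ± 0.146 in Th17 (adjusted p 0.000690 over the 4 groups). In 53618001 to 53619000 the Th2 share was 2.59% ± 0.610 against 0.683% ± 0.242 in Th0 (adjusted p 2.72e-06), with Th2 above Th0 in 3 of 3 runs at both. On chrM, which carries little or no such mark, 5hmC calls made up 0.629% to 2.48% of calls. Both calls held when any library was left out (largest adjusted p 0.0263) but not with limma (adjusted p 0.319 for both). Of 523 windows edgeR called 5 for 5hmC across Th0, Th1, Th2 and Th17, with 21 at an unadjusted p under 0.05, and limma called 0. The other 3 were a pair at Fignl2, where Th2 averaged 5.67% ± 9.81 and 3.28% ± 3.87, and 1 near Maf, and each was lost in some refit without a library. The count fell to 3 without Th0 1 or Th0 3 and to 2 without Th2 3. In the 100-kb tiles edgeR called 0 of 131 for 5hmC (3 at an unadjusted p under 0.05, limma 0), and 1 without Th2 2 or Th2 3.

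Th17 cells were compared with Th0 for the same question, and 5mC fell at Maf. Maf, on chromosome 8 from 115703253 to 115706894, encodes a transcription factor that promotes Il10 expression in Th17 cells. Its window 115703001 to 115704000 went from 93.4% ± 0.747 (SD, n = 3) in Th0 to 79.8% ± 1.64 (SD, n = 3) in Th17 (adjusted p 0.00226, at least 199 calls) and 115704001 to 115705000 from 84.5% ± 4.15 to 64.8% ± 1.27 (adjusted p 0.00777, limma 0.0509). A gain stood at Zfp362, a zinc-finger gene on the Treg list, where 128787001 to 128788000 on chromosome 4 rose from 48.2% ± 8.83 to 88.6% ± 1.58 (adjusted p 0.00224), on as few as 19 calls in a library.

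Further windows were called at a pair of cytokine genes and at Maf. At Ifng, the Th1 cytokine gene on chromosome 10 from 118441046 to 118445894, the window 118440001 to 118441000 just outside the gene went from 65.2% ± 5.26 (SD, n = 3) in Th0 to 44.3% ± 3.05 in Th17 (adjusted p 0.0236, limma 0.0753). The call was lost without Th0 2 (0.0555), Th0 3 (0.190), Th17 1 (0.0910), Th17 2 (0.0667) or Th17 3 (0.0611). At Il17a, which encodes the cytokine that names the Th17 fate, 20731001 to 20732000 on chromosome 1 went from 88.5% ± 2.98 to 79.7% ± 1.42 (adjusted p 0.0259, limma 0.0879), and this was lost without Th0 2 (0.145), Th0 3 (0.180), Th17 1 (0.103), Th17 2 (0.0903) or Th17 3 (0.0611). The third Maf window, 115705001 to 115706000, went from 14.9% ± 1.54 to 9.86% ± 0.203 (adjusted p 0.00871, limma 0.140) and was lost without Th0 1 (0.0512) or Th17 2 (0.0566).

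With edgeR, 13 windows of 1 kb were called lower and 2 higher in Th17 than in Th0, of 46 at an unadjusted p under 0.05, and limma called 7. The lower ones included 3 at Maf, 1 at Ifng and 1 at Il17a, and the higher ones were at Zfp362 and Gata3. The Gata3 window, 9876001 to 9877000, went from 2.53% ± 0.758 in Th0 to 5.31% ± 0.251 in Th17, while 5mC calls on chrM reached 3.15%. Its edgeR call was lost without Th0 1 (adjusted p 0.0936), Th0 3 (0.300), Th17 1 (0.0849), Th17 2 (0.160) or Th17 3 (0.113). Refits without a library called 8 to 10 windows, with 8 without Th17 2, and kept 8 of the 15 throughout, among them 2 at Maf and 1 at Zfp362. All 15 moved the same way in the 3 runs without overlap between the libraries, and windows without overlap made up 13% of the 523 against 10% by chance. None of the 15 was among the 16 windows called for Th2 against Th0. In the 100-kb tiles edgeR called 0 (7 at an unadjusted p under 0.05, limma 0). With the sequencing run as a block 1 tile was called, that of Rab2a, a gene of membrane traffic, at -45.3 points (adjusted p 0.0219).

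Th1 cells were compared with Th0, and no window passed. The window with the smallest p, 97112001 to 97113000 on chromosome 11, lay in Tbx21, which encodes the transcription factor that directs the Th1 programme (97098007 to 97115331). There 5mC was 90.5% ± 2.54 (SD, n = 3) in Th0 and 70.0% ± 3.83 (SD, n = 3) in Th1, lower in 3 of 3 runs (adjusted p 0.159, at least 81 calls). It passed with the run as a block (adjusted p 0.0128) and with the Th0 and Th1 libraries fitted alone (0.0225), while the other refits gave 0.135 to 0.853. At Ifng, the window 118440001 to 118441000 stood at 55.3% ± 10.2 in Th1 and 65.2% ± 5.26 in Th0 (adjusted p 0.978). EdgeR called 0 of 523 windows of 1 kb, with 26 at an unadjusted p under 0.05, and limma called 0. Of the 100-kb tiles it called 0 (8 at an unadjusted p under 0.05, limma 0). Without Th0 2 the tile of Denr, Ccdc62 and Hip1r was called at 15 points higher in Th1 (adjusted p 0.0120), and without Th1 1 the tile of Itgb3 and Efcab13 at 25.0 points (0.0388).

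**Figure D2:**
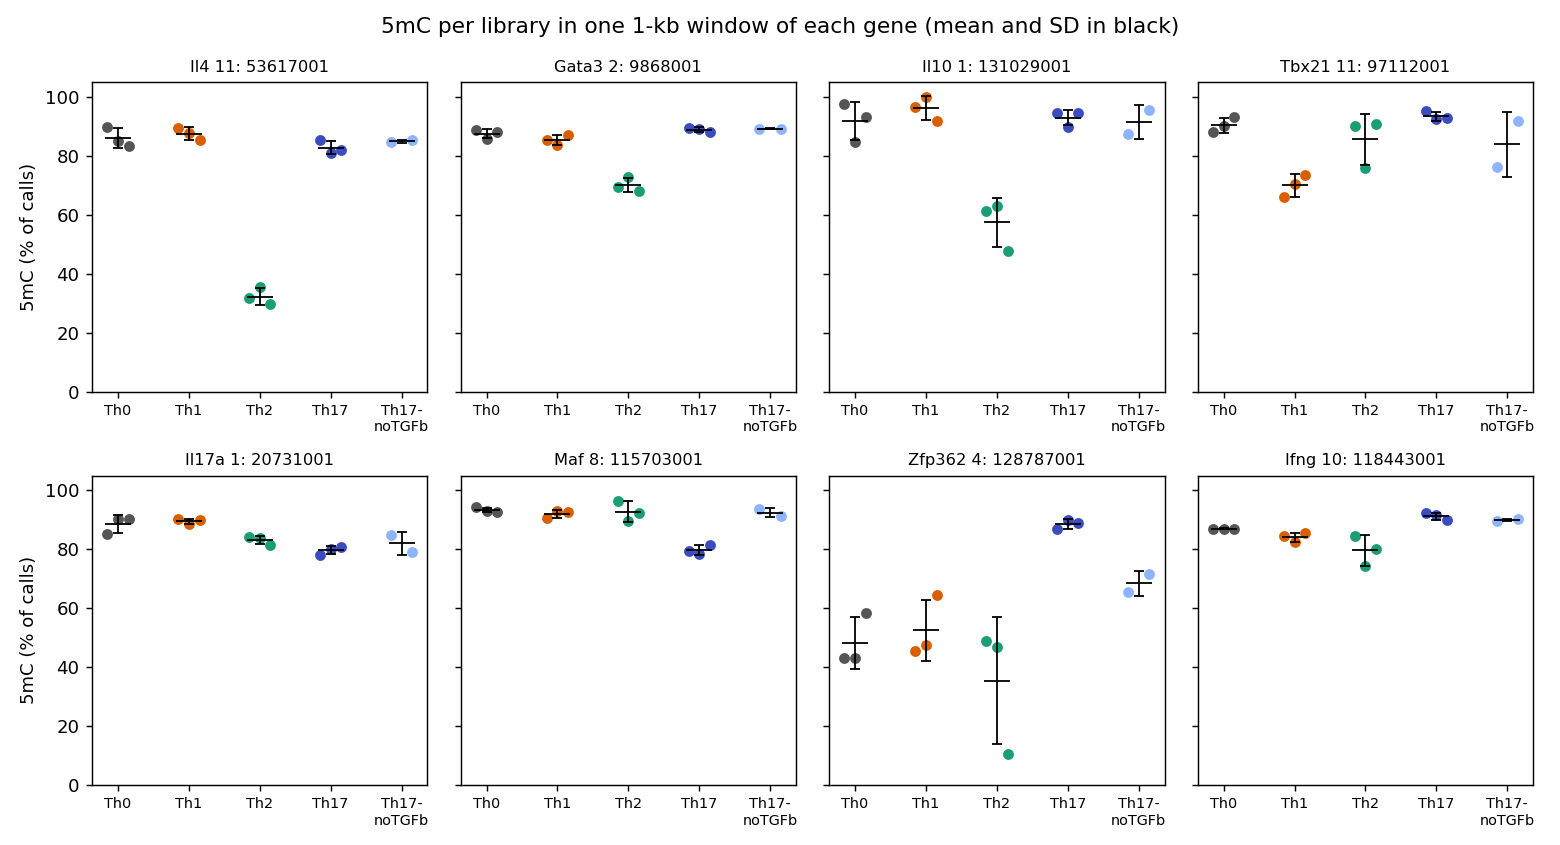
Share of calls that are 5mC (%) in each of the 14 libraries, in the 1-kb window with the smallest p across Th0, Th1, Th2 and Th17 at 8 genes. Points are libraries, and black marks give the mean and SD of the group. Th2 stands apart at Il4, Gata3 and Il10 and Th17 at Maf and Zfp362 (79.8% and 88.6%). At Tbx21 Th1 has the lowest mean (70.0%), but it was called there against Th17 and not against Th0 (edgeR adjusted p 0.159) or Th2 (0.117).

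The polarised groups were then compared with each other to ask which loci tell the fates apart. Tbx21 separated Th1 from Th17: the window 97112001 to 97113000 stood at 70.0% ± 3.83 (SD, n = 3) in Th1 and 93.6% ± 1.53 (SD, n = 3) in Th17 (adjusted p 0.00465, and 0.0674 without run 1). Ifng separated Th2 from Th17, with 79.6% ± 5.23 in Th2 and 91.2% ± 1.14 in Th17 at 118443001 to 118444000, inside the gene (adjusted p 0.000544, at least 156 calls). There Th1 stood at 84.1% ± 1.52, which differed from Th17 (adjusted p 0.0184) except without Th1 1 (0.0602), Th1 2 (0.101), Th17 1 (0.0784) or Th17 2 (0.0904). At Il4, 6 windows were lower in Th2 than in Th1 (12.8 to 55.3 points higher in Th1) and 7 lower in Th2 than in Th17.

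EdgeR called 13 windows of 1 kb between Th1 and Th2, 19 between Th1 and Th17 and 38 between Th2 and Th17, with 50, 58 and 76 at an unadjusted p under 0.05, and limma called 13, 9 and 35. In every refit without a library 11 of the 13, 6 of the 19 and 28 of the 38 were kept. The Th1 against Th17 count fell to 8 without Th1 1 or Th17 1 and to 6 without Th17 2. Libraries did not overlap in 15.9%, 17% and 19.3% of windows, against 10% by chance, and in every called window. With the run as a block 21 windows were called between Th1 and Th2. Those gained were 3 at Tbx21 (adjusted p 0.0290 to 0.0498), 1 at Il4 and 1 at Zfp362 (0.0123 each), 1 at Gata3 and 1 at Ppp1r3f (0.0332 each) and 1 with no gene (0.0498). In the 100-kb tiles the Il4 tile was called between Th1 and Th2 (16 points higher in Th1, adjusted p 1.3e-06) and between Th2 and Th17 (-15.3 points in Th2, 3.2e-06), with 0 tiles between Th1 and Th17 (5 at an unadjusted p under 0.05, limma 0). With the run as a block the Gata3 tile (-5.54 points in Th2, 0.0495) and the Rab2a tile (43.2 points higher in Th2, 0.0370) were called between Th2 and Th17 as well. The Th1 against Th2 comparison also called the Denr, Ccdc62 and Hip1r tile (15.8 points higher in Th1) and the Gata3 tile (6.49 points higher). These were lost with limma and in each refit that left out Th1 1 (adjusted p 0.0867 and 0.130), Th1 2 (0.151 and 0.197), Th1 3 (0.148 and 0.147), Th2 1 (0.168 and 0.0623), Th2 2 (0.0728 and 0.0652) or Th2 3 (0.0913 and 0.146). The Itgb3 and Efcab13 tile was called without Th1 1 against Th2 (0.0429) and against Th17 (0.0109).

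Th17-noTGFb cells were compared with Th17 and Th0 to place cells polarised without TGF-beta, a condition the labels describe as an intermediate phenotype. At Maf they stood near Th0, with 92.4% ± 1.54 (SD, n = 2) at 115703001 to 115704000, where Th17 had 79.8% ± 1.64 (adjusted p 0.0906). At 115704001 to 115705000 they had 82.5% ± 2.45 against 64.8% ± 1.27 in Th17 (adjusted p 0.251). Without run 1 these 2 Maf windows were called (adjusted p 0.0108 for each), as they were with only the Th17 and Th17-noTGFb libraries fitted (0.0127 for each). The Zfp362 window 128787001 to 128788000 stood at 68.4% ± 4.27, between Th0 and Th17. It was called against Th17 with only these groups fitted (adjusted p 0.0426, and 0.310 with all libraries). In the same fit a window on chromosome 17 from 39843001, with no protein-coding gene within 50 kb, was called too (-25.2 points, adjusted p 0.0127). Run 4 holds only this group, so the run and the missing TGF-beta cannot be told apart.

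Between Th17-noTGFb and Th17 edgeR called 0 windows of 1 kb (34 at an unadjusted p under 0.05, limma 0) and 0 tiles of 100 kb (4, limma 0). Against Th0 it called 2 windows (44, limma 1), of which a rise lay at Gata3, 9876001 to 9877000, from 2.53% ± 0.758 in Th0 to 6.97% ± 3.12, and 0 tiles (5, limma 0). The count fell to 0 without Th17-noTGFb 1. The Gata3 rise of 4.44 points was 2.23 points without Th17-noTGFb 1, where it was not called (adjusted p 0.823). The call was also lost without Th0 1 (0.0757) or Th0 3 (0.199). Fitting only the groups compared called neither. Libraries of 2 and 3 did not overlap in 24.7% of windows against Th17 and 25.6% against Th0, where chance gives 20%. No 100-kb tile was called for Th17 against Th0 or Th1, so the planned position of Th17-noTGFb over such tiles had no value. Over the 13 windows of 1 kb lower in Th17 than in Th0, pooled 5mC was 56.4% ± 2.80 in Th0, 41.8% ± 0.759 in Th17 and 51.0% ± 1.41 in Th17-noTGFb, which is 37.3% of the way to Th17 (44.1% without Th17-noTGFb 1 and 30.4% without Th17-noTGFb 2). By gene it was 18.4% over the 3 Maf windows, 74.6% at Il17a and 14.8% at Ifng. As a mean over windows, which weights each alike, it was 54.7%. Over the 14 windows lower in Th17 than in Th1 it was 14.9% pooled and 52.2% as a mean over windows. Over the 5 windows higher in Th17 than in Th1 it was 145% pooled and 55.4% as a mean over windows. Pooled values also depend on how the calls of each library are spread over the windows.

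Around the genes of the Th1, Th2, Th17 and Treg lists, the 5-kb windows asked where the 4 groups with 3 libraries differ at all. Of 1352 such windows around 90 genes, 56 could be tested and 13 differed, adjusted over the list alone, with 18 at an unadjusted p under 0.05, and limma called 13, of which 12 were shared. At Il4, 53615001 to 53620000 stood at 89.4% ± 0.389 (SD, n = 3) in Th0, 89.9% ± 1.11 in Th1, 65.2% ± 2.35 in Th2 and 87.9% ± 0.974 in Th17 (adjusted p 8.7e-09), and 53610001 to 53615000 passed too. Gata3 had 3 windows, from 9865001, 9870001 and 9875001, of which that from 9870001 stood at 50.2% ± 2.72, 54.0% ± 2.11, 34.2% ± 1.53 and 53.0% ± 1.98 (adjusted p 8.81e-05). Maf had 2, from 115700001 (adjusted p 0.0136) and 115705001 (0.00724). Zfp362 had 1, from 128785001 (0.00881), and Tbx21 had 1, from 97110001 (0.00881), where Th1 was lowest at 31.7% ± 1.87. Some of these windows differed only at low levels, near the 5mC share on chrM of up to 3.15%. That of Maf from 115705001 stood at 3.71% in Th0, 4.15% in Th1, 4.02% in Th2 and 3.06% in Th17. That of Gata3 from 9875001 stood at 4.22%, 4.49%, 2.51% and 5.03%. The Maf window from 115700001 was lost without Th17 2 (0.0831) or Th17 3 (0.0528), that from 115705001 with limma (0.0653) or without run 1 (0.0539), and the Zfp362 and Tbx21 windows without run 1 (0.0539 and 0.0980). Windows of 1 kb at the same genes gave 44 of 186 adjusted over the list alone, and windows of 1 kb anywhere gave 36 of 523. For Th17-noTGFb against Th17, 0 of the 56 were called (6 at an unadjusted p under 0.05, limma 0). The Maf window from 115700001 had an adjusted p of 0.162, 0.00755 without run 1 and 0.00439 with only the groups compared. The Tbx21 window from 97095001 was called without run 1 too (10.1 points higher in Th17-noTGFb, 0.0322, and 0.162 with all libraries).

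Whole gene regions, each gene with 5 kb on both sides, averaged out much of this. Of 135 regions, edgeR called Il4 and Gata3 lower in Th2 than in Th0. Il4 went from 90.9% ± 0.372 (SD, n = 3) to 75.2% ± 1.81 (adjusted p 5.62e-08, at least 3917 calls) and Gata3 from 32.4% ± 1.1 to 26.4% ± 2.79 (adjusted p 0.0288, limma 0.620, at least 7474 calls). Gata3 was lost without Th0 1 (0.118), Th0 2 (0.0768), Th0 3 (0.0559) or Th2 3 (0.0539). Rises in Th2 were called in single refits, at Syn3 without Th0 2 (28.0 points higher, 0.0185, and 0.277 with all libraries) and at Kpnb1 without run 1 (49.9 points higher, 0.0305, and 0.385 with all libraries). With the run as a block the Maf region passed in Th17 against Th0 (adjusted p 0.0151, and 0.659 without the block). EdgeR called 0 regions for Th1 against Th0 (4 at an unadjusted p under 0.05, limma 0), 0 for Th17 against Th0 (7, limma 0) and 0 for Th17-noTGFb against Th17 (5, limma 0). Adjusted over the list alone, the 10 tested members of the Th1, Th2, Th17 and Treg lists gave Il4 and Gata3 for Th2 (Gata3 0.00213, and 0.251 with limma) and 1 region for Th17 against Th0, which was kept without any single library but not with limma or without run 1. Maf was not called there (0.0957) but passed with the run as a block (0.00112) and with 5mC and 5hmC together (0.0437). Th1 against Th0 and Th17-noTGFb against Th17 gave no call over these members with edgeR or limma.

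As sets, the lists did not pass. Members with enough calls included Ifng and Tbx21 for Th1, Il4, Gata3, Maf and Il10 for Th2, Il17a for Th17 and Foxp3 and Zfp362 for Treg. Camera called 0 of the 16 tests of these 4 lists in 4 comparisons, with a smallest adjusted p of 0.134 for the Th2 list in Th2 against Th0 (0.574 with an estimated correlation, so no call was made with either). The naive T and T cell core lists had 1 tested member each, Foxp1 and Skap1, and the other 10 lists had 0, so they were not tested.

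Foxp3, on chromosome X from 7579676 to 7595243, encodes the factor that defines regulatory T cells and served as a locus outside these fates. None of the 11 windows of 1 kb at the gene was called with edgeR in any of the 8 comparisons. The window with the smallest p in Th2 against Th0, 7584001 to 7585000, stood at 97.9% ± 2.00 (SD, n = 3) in Th2 and 89.7% ± 4.35 in Th0 (adjusted p 0.203, at least 15 calls). The whole Foxp3 region stood at 83.4% ± 2.37 in Th0, 83.8% ± 2.22 in Th1, 83.5% ± 7.61 in Th2 and 83.5% ± 2.65 in Th17, on at least 445 calls. X sequence was more abundant in the run 1 libraries, at 3.71% of autosomal calls against 2.36% in the others. At the Foxp3 window 7579001 to 7580000 every run 1 library had more 5mC than any other library. Without run 1 the window from 7584001 had an adjusted p of 0.567 (0.153 to 0.567 over all refits). In the window 7565001 to 7566000 of the neighbouring Ppp1r3f, the 3 Th2 libraries stood at 69.2%, 8.47% and 4.35% and those of Th0 at 73.3%, 61.2% and 80.0% (adjusted p 0.147). It was called as 64.2 points lower in Th2 without run 1 (adjusted p 0.000444, and 0.000262 against Th1 and 0.00101 against Th17) and without Th2 1 alone (7.79e-05), while the other refits against Th0 gave 0.0654 to 0.661. Against Th1 it passed with the run as a block (0.0332, and 0.0894 without the block). The Th2 cytokine genes Il5 and Il13, the Th17 cytokine gene Il17f and the receptor genes Il2ra and Ctla4 had fewer than 10 calls in some library, with median calls of 0 at Il5 and Il2ra, 13 at Il13 and 2.5 at Il17f and no covered CpG at Ctla4. Differences at these genes could not be assessed at this depth.

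Across all calls on the autosomes and X, 5mC made up 77.6% ± 1.04 (SD, n = 3) in Th0, 77.6% ± 0.755 in Th1, 77.4% ± 0.316 in Th2, 77.2% ± 1.12 in Th17 and 76.8% ± 0.238 (SD, n = 2) in Th17-noTGFb. On chrM, the background of the calling, it was 0.314% to 3.15%. 5hmC made up 1.76% ± 0.540 in Th0, 1.92% ± 0.916 in Th1, 1.77% ± 0.587 in Th2, 1.52% ± 0.507 in Th17 and 1.83% ± 0.320 in Th17-noTGFb, and outside the deep tiles it was at or below the chrM share of the same library in 13 of 14. The exact permutation tests, two-sided, gave adjusted p of 1 for each of the 7 comparisons of 5mC and 0.9 for each of 5hmC, and with 3 against 3 or 2 against 3 libraries no such test can go below 0.1. Within the 3 runs, 5mC over all calls was higher in Th1 than in Th0 in 2 and higher in Th17 than in Th0 in 1. Outside the deep tiles it was higher in Th1 than in Th0 in 3 (0.554 points, exact permutation p 0.5). There Th17 stood at 81.9%, 79.6% and 80.3% in runs 1 to 3 and Th0 at 81.3%, 80.2% and 79.8%. Over all calls and outside the deep tiles, 5hmC was lower in Th17 than in Th0, Th1 and Th2 in all 3 runs. Over CpGs covered in every library, however, Th17 stood above Th0 in 1 run and Th1 and Th2 above Th17 in only 2 each. As a mean over CpGs with coverage of at least 5, Th17 stood above Th0 and Th1 in run 1. Over all calls, with the run as a block, the exact sign-flip p for Th17 against each of these groups was 0.25, the smallest that 3 runs allow. The runs themselves differed, with 5mC means of 78.2%, 77.6%, 76.6% and 76.8% and 5hmC means of 1.11%, 1.75%, 2.37% and 1.83% in runs 1 to 4.

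The broad layout was that of mammalian genomes, where gene starts are kept unmethylated. CpGs within 1 kb of either end of a protein-coding gene had a median 5mC over libraries of 34.7%, those inside genes 82.6% and those outside 82.9%, on at least 48537, 177051 and 199667 calls per library. Autosomes stood at 77.4% and chromosome X at 79.9%. Ends of imprinted genes, where the parental copies differ, had a median of 36.5% but ranged from 6.74% to 100% on at most 310 calls.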

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

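All tests in this part were chosen after the result was seen. They use chromosome Y, chrM, the deepest tile and 5hmC by run, which no comparison of groups used, and a signal there above the level in the other libraries, or above none at all, is what marked these results.

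The 4 run 1 libraries, one of each of Th0, Th1, Th2 and Th17, held less Y and more X sequence than the other 10. At CpGs with shallow coverage, Y calls averaged 0.300% of autosomal calls in run 1 (0.197% to 0.507%) and 0.970% in the others (0.693% to 1.17%), and X calls 3.71% (3.24% to 4.32%) and 2.36% (2.16% to 2.60%). Of 20 X windows of 1 kb, the lowest run 1 library lay above the highest other library in 7, and in the window with the largest gap, picked for it, at Ppp1r3f from 7574001 to 7575000, 5mC was 35.1% in run 1 (28.0% to 42.3%) and 1.58% in the others (0.218% to 2.78%), a gap of 25.2 points against at most 2.45 in the 503 autosomal windows. At CpGs near autosomal gene ends run 1 differed by 0.0489 points (SD over libraries 1.42), while those near X gene ends stood at 59.2% and 43.8%. Outside the deep tiles, however, 5mC on the autosomes and X was 81.3% to 82.2% in the run 1 libraries and 79.6% to 80.6% in the others. The autosomal values show no shift of the size seen near X gene ends, but a smaller shift of 5mC calling in the whole run stays open. DNA of female cells, whose inactive X carries methylated islands, may be mixed into run 1, with a male share of 31.0% by Y and 42.9% by X, although the labels say male for every sample, and the design gives no biological group to set against it.

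The share of 5hmC calls differed between runs. Outside the deep tiles the share averaged 0.477%, 0.866%, 1.11% and 0.907% in runs 1 to 4, so that run 3 stood 2.34 times as high as run 1, which argues against the deepest tile as the whole source of the run difference. False calls at the rate seen on chrM may be the cause and stay open, since the nuclear share over the chrM share of the same library was 1.95 times as high in run 3 as in run 1 (exact permutation p 0.0286, 4 libraries each, the smallest it can give), but with a 95% interval from the spread between libraries of 0.936 to 4.07. A change between runs in the calling of nuclear DNA was not tested, and no biological explanation was tested because runs 1 to 3 each hold Th0, Th1, Th2 and Th17 and run 4 only Th17-noTGFb. On chrM the median share was 1.74%, and outside the deep tiles the nuclear share was at or below the chrM share of the same library in 13 of 14 (the exception was Th2 2, at 0.823% and 0.629%), so that 5hmC outside the deep tiles was not told apart from the background of the calling.

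The tile from 3000001 to 3100000 on chromosome 9 holds no annotated protein-coding gene and was read 841 times as deeply as the library median. There 5hmC made up a median of 22.9% of calls (17.4% to 25.1%), against 0.501% to 2.04% in the other deep tiles. The 5hmC share over all calls, a median of 1.69% over libraries, includes this tile, and outside the deep tiles the median was 0.884%. The cause of the depth and of the 5hmC share of this tile was not tested.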

How the results depend on the processing

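Alternatives with 1-kb or 2-kb windows, gene ends, without run 1, 5mC with 5hmC, without deep tiles and for the position of Th17-noTGFb were chosen after the data were seen, and the others before. Of 221 settings for the main results other than leaving out a library, 165 were scored as keeping the result and 0 as reversing it. The others were scored as stronger (27), weaker (15) or moved (14). Counts of calls cannot change sign, so no reversal was possible for results given as counts. This score allowed small changes of a count, such as from 3 to 2 tiles for Th1 against Th2 with the run as a block. Where a result moved the cause was not tested unless given.

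In 100-kb tiles, Th2 against Th0 gave 2 calls with a minimum of 20 calls and 2 with limma, and Th1 against Th2 gave 1 with limma. Of 1-kb windows 523 could be tested, against 131 tiles of 100 kb, and the cause of their larger counts was not tested. These counts were 16 for Th2 against Th0, 15 for Th17 against Th0, 13 for Th1 against Th2, 19 for Th1 against Th17, 38 for Th2 against Th17 and 2 for Th17-noTGFb against Th0. In gene regions, Th2 against Th0 gave 1 with limma, 1 with the library offset, 1 with only the groups compared and 1 with gene ends, and Th17 against Th0 gave 2 with gene ends. Listed-gene windows gave 25 of 2 kb and 44 of 1 kb, and for Th17-noTGFb against Th17 they gave 2 without run 1, 1 with only the groups compared, 1 of 2 kb and 1 of 1 kb.

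In 1-kb windows, limma called 7 for Th17 against Th0, 9 for Th1 against Th17 and 1 for Th17-noTGFb against Th0. Only the groups compared gave 1 for Th1 against Th0, 8 for Th17 against Th0, 11 for Th1 against Th17, 4 for Th17-noTGFb against Th17 and 0 for Th17-noTGFb against Th0. Without run 1, Th1 against Th17 gave 10, Th17-noTGFb against Th17 gave 2 and against Th0 gave 1, as did a minimum of 5 calls. For 5hmC, tiles gave 1 with the library offset, 1 without run 1 and 5 with 1-kb windows, of which limma called 0.

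With the sequencing run as a block, which pairs the libraries of a run, tiles gave 1 for Th17 against Th0 and 3 for Th2 against Th17, gene regions 2 for Th17 against Th0, 5hmC tiles 2, and 1-kb windows 1 for Th1 against Th0 and 21 for Th1 against Th2. Smaller changes were 2 tiles for Th1 against Th2 (3 without the block) and 4 windows of 1 kb for 5hmC (5 without it). Other 1-kb counts were 14 for Th17 against Th0 (15 without it), 22 for Th1 against Th17 (19) and 39 for Th2 against Th17 (38). The rest of the main results that the block could be run on kept their counts, and among the named windows it changed the call of 5.

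Leaving out each library in turn gave 0 to 1 tiles for Th1 against Th0, 1 to 2 for Th2 against Th0, 1 to 2 for Th1 against Th2 and 0 to 1 for Th1 against Th17, 1 to 2 gene regions for Th2 against Th0, and 0 to 1 tiles and 2 to 7 windows of 1 kb for 5hmC. Windows of 1 kb ran from 8 to 10 for Th17 against Th0, 6 to 15 for Th1 against Th17 and 0 to 2 for Th17-noTGFb against Th0, and the Th17-noTGFb position from 30.4% to 44.1%. A group left with a single library was assumed to vary like the others.

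The largest difference of the 7 comparisons in global 5mC was 0.409 points, for Th1 against Th17. Outside the deep tiles it was 0.554, for Th1 above Th0. Over CpGs covered in every library it was 2.08, for Th2 below Th0, with Th1 against Th17 at 0.937, and as a mean over CpGs with coverage of at least 5 it was 5.75, for Th2 below Th17, with Th1 against Th17 at -2.67. In 5hmC it was 0.405 points, for Th1 against Th17, and 1.49 for the same comparison over CpGs covered in every library. As a mean over CpGs with coverage of at least 5, 5hmC differed most between Th2 (3.01%, 3.39% and 2.83%) and Th17 (1.91%, 2.76% and 2.18%). The Th17-noTGFb position became 54.7% as a mean over windows, and 64.7%, 55.3% and 55.9% with windows chosen without Th17 1, 2 and 3. For windows of Th17 against Th1 it became 52.2% as a mean over windows. Pooling weights the windows by the depth of each library, and the cause of the difference was not tested. With coverage of at least 5, medians were 33.1% near gene ends, 69.9% inside genes, 72.3% outside, 62.2% on autosomes and 62.4% on X, and the deep tiles averaged 62.2%. This filter leaves mostly enriched loci, and the cause of these changes was not tested.

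The next larger tile size and promoters as planned were not run, since 100 kb is the largest size and the annotation has no strand. The position over 100-kb tiles had no value because 0 were called, and imprinted gene ends had no CpG with coverage of at least 5. Depth limits the tests to the enriched loci, and a change elsewhere was not detectable.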

Other observations

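The tests of Maf in Th17-noTGFb were chosen after the result was seen, as were the splits over 1-kb windows and those drawn within runs, while the splits over tiles, gene regions and listed-gene windows were planned.

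Without TGF-beta, 5mC was hardly lost at Maf. In percent of the mean Th17 fall from Th0, averaged over the 3 Maf windows called lower in Th17, the Th17-noTGFb libraries had fallen by 2.43% and 18.7% and the 3 Th17 libraries by 92.5% to 108% (exact permutation p 0.1, two-sided, the smallest that 2 against 3 allow). The same Th17 libraries set the windows and the scale, which puts them near the full fall by construction and favours a small p. A shift of run 4 at every window is argued against by the 478 windows called in no comparison, where Th17-noTGFb minus Th17 had a median of -0.106 points (5th to 95th percentile -8.01 to 7.79), against a mean of 11.4 points (3.95 to 17.7) at the Maf windows. With windows chosen without a Th17 library, Th17-noTGFb had 0.238% to 20.2% of that library's fall at Maf. These values are consistent with the hypothesis that loss of methylation at Maf needs TGF-beta, but a run 4 effect at single loci stays open because the run holds no other group, and between Th17-noTGFb and Th17 the fit of all 14 libraries called no Maf window, while the fit of these groups alone called 4 windows, of which 2 were at Maf (adjusted p 0.0127 each).

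At Il4 the largest loss of 5mC and the largest gain of 5hmC in Th2 lay in different windows. At 53617001 to 53618000, where 5mC was lowest in Th2, 5hmC was 2.23%, 0.758% and 1.46% in the 3 Th2 libraries. At 53615001 to 53616000, where 69.5% of calls were still 5mC, 5hmC was 3.49%, 3.30% and 2.99%. The difference between these windows was not tested.

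Other splits of the libraries of a comparison were counted. With 3 against 3 there are 10 splits, too few for a share under 0.05. In 100-kb tiles, Th1 against Th0 had 0 calls and the highest other split 0, with as many in all 10 splits. Th2 against Th0 had 1 and the highest other split 1, with as many in 2 splits. Th17 against Th0 had 0 and the highest other 0, as many in 10. Th1 against Th2 had 3 and the highest other 1, as many in 1. Th1 against Th17 had 0 and the highest other 1, as many in 10. Th2 against Th17 had 1 and the highest other 0, as many in 1. In 1-kb windows the real counts of 16, 15, 13, 19 and 38, for Th2 and Th17 against Th0, Th1 against Th2, Th1 against Th17 and Th2 against Th17, stood against highest other splits of 0, 0, 3, 1 and 0, with as many in 1 split each, and Th1 against Th0 had 0 and the highest other 0, as many in 10. In gene regions Th2 against Th0 had 2 and the highest other 0 (as many in 1), Th1 against Th0 had 0 and 0 and Th17 against Th0 had 0 and 2 (as many in 10 for both).

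The pairing leaves 4 splits that, like the real one, put a library of each run on each side, and the highest of the other 3 gave 0 calls in each of these 15 comparisons. Across Th0, Th1, Th2 and Th17, 100 splits were counted that ignore the run and 100 that exchange groups only within a run, with the real split in each. The 13 listed-gene windows were reached in 1 of the 100, the real one, in both sets, with 6 as the highest other and 9 within runs, which argues against chance for the count. The 5 windows of 1 kb with 5hmC were reached in 4 of 100 splits, with 8 as the highest other. Within runs they were reached in 3 of 100, with 5 as the highest other. These shares are under 0.05 without adjustment for the number of split tests. They do not exclude chance, as these windows were chosen after the data were seen and limma called 0. The 0 tiles with 5hmC were reached in all 100 of both sets, with 2 as the highest other and 1 within runs.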
